A study of Mus musculus with 15 samples.

How the data were processed

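RNA was sequenced from mouse hematopoietic stem and progenitor cells kept in culture, in 5 groups of 3 libraries. Per the labels, stem cells sorted from bone marrow grew for 11 days in medium based on polyvinyl alcohol with SCF at 10 ng/mL and TPO at 100 ng/mL, and the sorted progeny were lysed for RNA. Libraries came from 2 ng of RNA with the SMART-Seq v4 kit, which amplifies full-length cDNA and does not mark the strand. The 4 groups from 4 month old donors were a vehicle group in PBS (young vehicle), a group given recombinant Thbs1 (rThbs1), a group given rThbs1 with the neutralizing antibody A4.1 (A4.1 group) and a group given rThbs1 with an IgM antibody (IgM group). The remaining group was vehicle-treated cells from 18 month old donors (aged vehicle). The treatment field of rThbs1 replicates 2 and 3 reads rThbs2 and rThbs3, while their titles read rThbs1, and they were grouped by title. The sample descriptions place the 12 young libraries in a set named TSP and the aged libraries in a set named NTN.

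The deposited values are FPKM, read values scaled to gene length and library size, computed by the authors. Per the submitters' processing notes the reads were examined with FastQC 0.11.5, aligned with STAR to GRCm38 (mm10), and handled in edgeR; the versions of STAR and edgeR, the annotation, the strand setting and any scaling between libraries are not stated. The table holds 20696 genes in 15 libraries, all 20696 gene IDs were found in GENCODE vM21 (GRCm38), 6 have no symbol there, and 1045 genes are listed at 0 in every library. Counts were not used here, and depth was estimated from the step between possible FPKM values of genes shorter than 800 bases at 0.5 FPKM or more. The depth was accepted where these values were whole numbers of reads within 0.1, and 83.1% to 100% of them were.

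Values were analysed as log2(FPKM + 1) with limma 3.58.1 (lmFit, then eBayes with trend) in R 4.3.3, as deposited and with no further scaling. The 12 young libraries shared 1 model of group means with 8 residual degrees of freedom and a prior of 7.34, over the 10932 genes with a mean of at least 1 FPKM. The aged comparison used all 15 libraries, with 10 residual degrees of freedom, a prior of 6.06 and 11224 genes. Tests were two-sided, adjusted by Benjamini-Hochberg within each comparison, and called at an adjusted p under 0.05. Log2 fold changes are given with the standard error (SE) of the fit, and FPKM as mean ± SD. The 8 comparisons were rThbs1 against young vehicle, A4.1 against IgM, A4.1 against rThbs1, A4.1 against young vehicle, IgM against young vehicle, IgM against rThbs1, the mean of rThbs1 and IgM against the mean of young vehicle and A4.1 (unblocked rThbs1 against the rest, 6 libraries against 6), and aged against young vehicle. Across genes, the effects of rThbs1 and of A4.1, and of age and of rThbs1, were compared by Pearson r, Spearman rho and covariance, with a jackknife SE over left-out libraries. The covariance that shared control libraries give was simulated in 100 draws.

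Gene lists were tested with limma camera at a preset inter-gene correlation of 0.01, adjusted over the lists with at least 5 tested members, and again with an estimated correlation. The lists were HSC identity, HSC ageing signature, TGF-beta and SMAD targets, NF-kB and inflammatory genes, interferon response, antigen presentation, S phase, G2/M phase, p53 targets and cell cycle inhibitors, MYC and ribosome biogenesis, cytosolic ribosomal proteins, oxidative phosphorylation, mitochondrially encoded transcripts, glycolysis and hypoxia, cholesterol synthesis, integrated stress and unfolded protein response, immediate early genes, lysosome and autophagy, thrombospondin receptors and partners, megakaryocyte and platelet, erythroid, neutrophil and granule, monocyte with macrophage and dendritic, mast cell and basophil, eosinophil, lymphoid, endothelial and stromal, cell adhesion and motility, histone genes, heat shock, and red-ox with NRF2. Members were also counted as called over all genes and adjusted over the list alone.

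Genes were named by a rule. For rThbs1 against young vehicle, A4.1 against IgM, unblocked rThbs1 against the rest and aged against young vehicle it took 10 fixed genes (Thbs1, Cd36, Cd47, Procr, Hlf, Mecom, Selp, Serpine1, Cdkn1a, Mki67). It added the 6 highest and 6 lowest log2 fold changes among called genes whose libraries did not overlap, leaving out unnamed gene models. It then took up to 2 members of smallest adjusted p from at most 8 lists with called members. The other comparisons took the 3 highest and 3 lowest, or the 5 of smallest p where none was called, and any of the 4 members of smallest p could stand for a list that passed. In the aged comparison the lowest by this rule were listed at 0, so the 6 lowest of the other genes were added after their values were seen. Serpine1 was not analysed here, as it has no values. Coordinates are those of the whole gene in GRCm38.

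Alternatives were a log2 fold change of at least 1, pseudocounts of 0.1 and 0.5, no filter, a filter at 5 FPKM, rescaling each library to the same total (TPM), median-of-ratios scaling, quantile normalization, eBayes without trend or with the robust option, arrayWeights, a fit of only the compared groups, the replicate number as a block, and each library left out in turn. Further alternatives, chosen after seeing the data, were a spline correction of each library for GC content and gene length, a term for libraries with Xist above 1 FPKM, nuclear protein-coding genes only, leaving out the 3 libraries with the most AT-rich values, and leaving out genes listed at 0 in the aged libraries. GC content was available for 20688 genes.

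The pipeline was tested on simulated data with the spread of these libraries, 100 genes changed by a log2 fold change of 1 and 100 changed by 2 in each comparison. In rThbs1 against young vehicle 84 of the 100 smaller and 97 of the 100 larger changes were called, with 13 calls among unchanged genes. Across the other comparisons these were 77 to 95, 95 to 99 and 4 to 14. A shifted list passed in every comparison, and the other lists passing numbered 0, or 1 in A4.1 against young vehicle. Genes were simulated independently, so this does not test lists whose members vary together. Preparation and figures used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.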

Results

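RNA was sequenced from cultured mouse hematopoietic stem and progenitor cells in 5 groups of 3 libraries. The groups were young vehicle, rThbs1, A4.1 (rThbs1 with its neutralizing antibody), IgM (rThbs1 with an IgM antibody) and aged vehicle. Thbs1, thrombospondin 1, is a secreted matrix protein that binds Cd36 and Cd47 on the cell surface. The estimated depth was 17.4 to 22.7 M reads in 11 of the 12 young libraries, 40.6 M in rThbs1 replicate 2, and 37.8, 51.9 and 67.3 M in the aged libraries. Between 10564 and 11272 genes reached 1 FPKM in each library, and replicates of a group correlated at 0.968 to 0.995. Gm23935, a gene model of the miRNA class in the annotation, held 10.2% to 24.6% of the FPKM total in the young libraries and was listed at 0 in the aged libraries. Xist, the long RNA of the inactive X chromosome, was at 14.0, 7.76, 13.9 and 7.38 FPKM in replicate 3 of young vehicle, rThbs1, A4.1 and IgM, and at most 0.05 in the other libraries. Mki67, a proliferation marker, was at 9.32 FPKM in IgM replicate 1 and at 0.39 to 1.31 in the other libraries. Values rose with AT content most in IgM replicate 1, with a slope of -3.62 log2 units per unit of GC content, then in rThbs1 replicate 1 (-1.71). The slope of A4.1 replicate 1 was 2.05. Nothing in the labels says that replicates came from separate animals, so p-values measure only the spread between these samples.

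The comparison of rThbs1 with young vehicle asked what added Thbs1 changed in these cells. Of 16 immediate early genes, the genes that respond first to a stimulus, 3 fell with rThbs1. Jun, an AP-1 subunit, fell from 21.5 ± 6.77 to 4.00 ± 1.04 FPKM (SD, n = 3 and 3; log2 fold change -2.15, SE 0.24, adjusted p = 0.00192; ENSMUSG00000052684, GRCm38 chr4:95049034-95052222). Fos, its AP-1 partner, fell from 18.9 ± 1.40 to 6.88 ± 1.74 FPKM (log2 fold change -1.36, SE 0.23, adjusted p = 0.0256; ENSMUSG00000021250, chr12:85473890-85477273). S100a4, a calcium-binding protein linked to cell motility, fell from 28.9 ± 1.37 to 9.74 ± 2.20 FPKM (log2 fold change -1.49, SE 0.21, adjusted p = 0.0125; ENSMUSG00000001020, chr3:90603771-90606045). Of 10932 genes tested, 30 fell and 0 rose (limma; 1577 genes at an unadjusted p under 0.05), 17 of the 30 were protein coding, and all 30 had groups that did not overlap, where chance gives 10% of genes and 19.6% of all genes did so. With quantile normalization 5 genes were higher and 26 lower, and with a correction for GC content and gene length 3 and 21.

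Of the immediate early list 10 members fell with rThbs1 when adjusted over the list alone, beside the 3 called over all genes. The list's median log2 fold change was -0.45 (-0.204 after TPM rescaling, with 3 lower over the list alone), and its test held with an estimated correlation (adjusted p = 0.0217). With the replicate number as a block that adjusted p was 0.0513. Dusp1, a phosphatase that switches off MAP kinases, fell by a log2 fold change of 0.74 (adjusted p = 0.0436), and Egr1, a zinc finger transcription factor, was at -0.98 without passing (adjusted p = 0.0507). Zfp36, which speeds the decay of inflammatory mRNAs, changed by -0.89 (adjusted p = 0.0336), and Btg2, an antiproliferative p53 target, by -0.85 (adjusted p = 0.049). Nkg7, a granule membrane protein of cytotoxic cells, fell from 360 ± 43.7 to 211 ± 4.48 FPKM (adjusted p = 0.0256). Nsdhl, an enzyme of sterol synthesis, fell from 56.2 ± 2.58 to 33.9 ± 0.567 FPKM (adjusted p = 0.0256). Among histone genes 3 of 19 fell, and 11 fell when adjusted over the list alone (median -0.69; adjusted p = 0.104 with an estimated correlation). These included the linker histones H1f5 (-1.07, adjusted p = 0.0256) and H1f2 (-0.85, adjusted p = 0.0436) and the core histone H2ac6 (-1.26, adjusted p = 0.0256). H2bc8, another core histone gene, was at -1.51 (adjusted p = 0.0436). The histone median was -0.437 after correction for GC content and gene length. Ribosomal RNA gene models, of which 1 was called, summed to 578, 1609 and 1018 FPKM with rThbs1 and 2653, 4499 and 2992 in vehicle. Rn7sk, a small nuclear RNA, was at 24.45, 39.91 and 39.23 FPKM against 54.7, 88.2 and 68.32. These values were not tested as a group, nor was a difference between libraries in the capture of RNA without poly(A) tails. The mitochondrial ribosomal RNA mt-Rnr1 fell by a log2 fold change of 1.69 (adjusted p = 0.0256) and mt-Nd3, a subunit of respiratory complex I, by 0.75 (adjusted p = 0.0358).

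For the 47 cytosolic ribosomal proteins the median was -0.56, with 0 called over all genes and 42 lower when adjusted over the list alone (adjusted p = 0.337 with an estimated correlation). It was -0.297 after TPM rescaling (29 lower) and -0.241 with quantile normalization (25 lower and 1 higher). Rps12 was at -0.99 (adjusted p = 0.0966) and Rpl7a at -0.71 (adjusted p = 0.0989). The cholesterol synthesis list had a median of -0.32, with 1 of 25 members lower, and 8 when adjusted over the list alone (adjusted p = 0.315 with an estimated correlation). Pmvk was at -0.69 (adjusted p = 0.0808) and Mvk at -0.65 (adjusted p = 0.113), both kinases of the mevalonate pathway. Oxidative phosphorylation passed at a median of -0.21 with 0 of 41 members called and 10 lower adjusted over the list alone (adjusted p = 0.507 with an estimated correlation). Mitochondrially encoded transcripts passed at -0.54, with 1 of 9 lower (adjusted p = 0.43 with an estimated correlation). Interferon response passed on the higher side at a median of 0.26 with 0 of 32 members called (adjusted p = 0.337 with an estimated correlation), and its member Ifit1 was at 0.78 (adjusted p = 0.258). MYC and ribosome biogenesis (0.25, adjusted p = 0.402 with an estimated correlation) and lysosome and autophagy (0.12, adjusted p = 0.521 with an estimated correlation) also passed on the higher side without a called member. The p53 list passed on the lower side with a median of -0.01, a mean of -0.12 and 1 of 24 members called, 2 adjusted over the list alone (adjusted p = 0.507 with an estimated correlation). Neutrophil and granule (-0.42), erythroid (-0.20) and lymphoid (-0.29) lists passed on the lower side, with 3 of 10, 3 of 10 and 1 of 5 members lower adjusted over the list alone. They lost the call with adjusted p = 0.402, 0.147 and 0.402 with an estimated correlation. The erythroid median was -0.0615 without young vehicle replicate 3, and the lymphoid median -0.458 and -0.142 without young vehicle replicates 1 and 2 and -0.518 and -0.0842 without rThbs1 replicates 2 and 3. For p53 it was -0.0616 and -0.186 without those vehicle replicates and -0.174, -0.0414 and -0.0515 without rThbs1 replicates 1, 2 and 3. Without rThbs1 replicate 1 it was 0.160 for MYC and -0.124 for oxidative phosphorylation, and without young vehicle replicate 1 it was 0.183 for lysosome. TPM rescaling turned the p53, oxidative phosphorylation and erythroid medians to 0.283, 0.0601 and 0.0457, where the median of all genes was 0.267. HSC identity, HSC ageing signature, TGF-beta and SMAD targets, NF-kB, antigen presentation, S phase, G2/M phase, glycolysis, stress response, thrombospondin receptors, megakaryocyte, monocyte, mast cell, adhesion, heat shock and red-ox lists did not pass, at adjusted p of 0.195 to 0.993. The median and mean differed in sign for the TGF-beta and antigen presentation lists. The eosinophil list had 2 testable members and the endothelial and stromal list 3, too few to test in any comparison.

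Among the fixed genes, Cdkn1a, the cell cycle inhibitor p21, was at 266 ± 12.3 FPKM with rThbs1 and 339 ± 11.4 in vehicle (log2 fold change -0.35, adjusted p = 0.188). Procr (-0.05, adjusted p = 0.928) and Hlf (0.03, adjusted p = 0.961), markers of long-term stem cells, did not pass. Neither did Selp (-0.02, adjusted p = 0.976), a stem cell ageing marker, Cd47 (-0.10, adjusted p = 0.787) or Mki67 (-0.08, adjusted p = 0.962). Thbs1 was listed at 0 in all rThbs1 libraries and at 0.117 ± 0.133 FPKM in vehicle, below the filter, as were Cd36 (0.0667 and 0.06) and Mecom (0.937 and 0.593). Serpine1 was not analysed here. The count of 30 was 5 higher and 21 lower without young vehicle replicate 1, 9 without young vehicle replicate 2, 1 without young vehicle replicate 3 or rThbs1 replicate 3, 2 without rThbs1 replicate 1, 82 without rThbs1 replicate 2 and 18 without A4.1 replicate 3. Of the 14 called genes under the naming rule 1, Jun, kept its call without each library. The estimated-correlation p of the immediate early list, 0.00605 to 0.116 over 28 alternatives, was not under 0.05 in 9 of them, among these 0.0752 without young vehicle replicate 1 and 0.0588, 0.0907 and 0.0546 without rThbs1 replicates 1, 2 and 3, and 0.10001 after TPM rescaling.

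**Figure D1:**
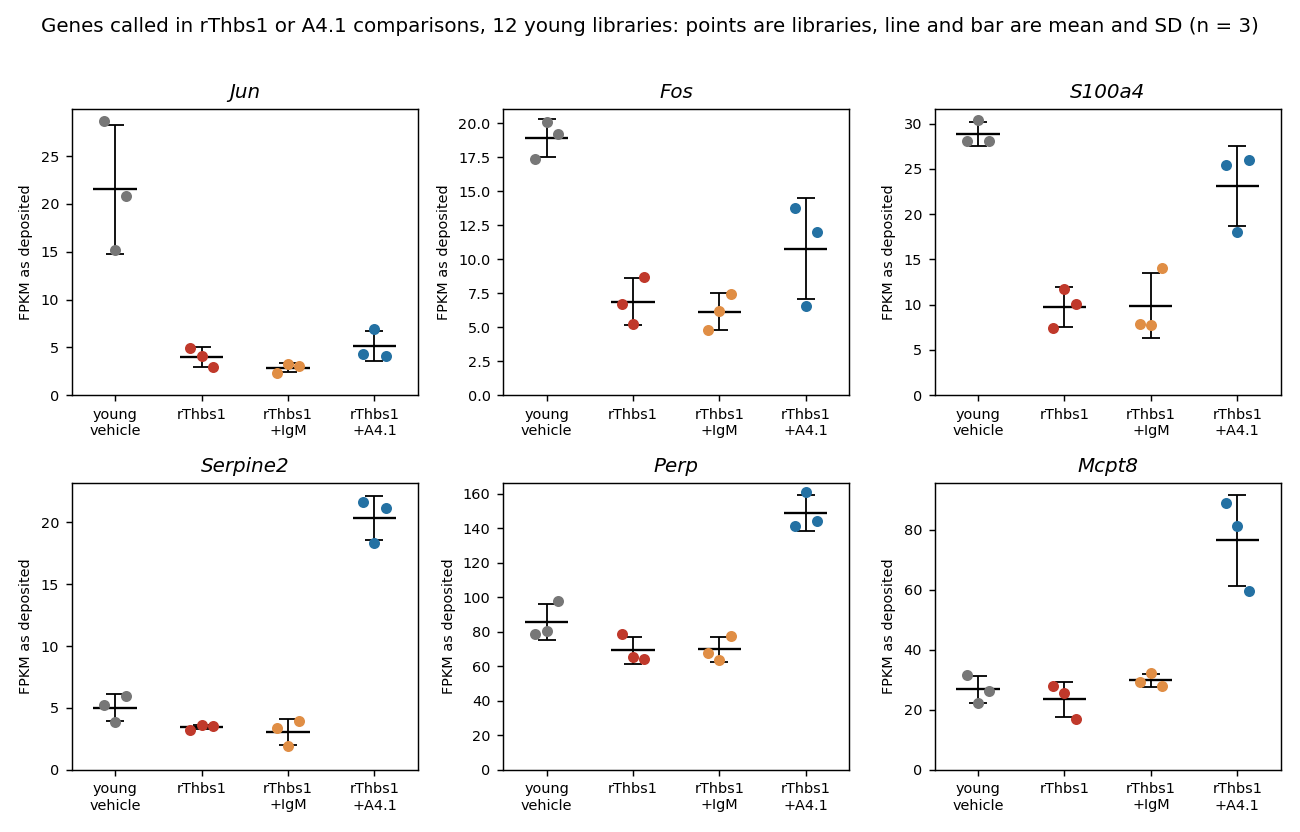
FPKM of Jun, Fos, S100a4, Serpine2, Perp and Mcpt8 in each library of the 4 young groups, with the group mean and SD (n = 3). Jun lies at a mean of 21.5 FPKM in young vehicle against 4.00 with rThbs1, and Serpine2 at 20.4 in the A4.1 group against 3.07 in the IgM group.

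The comparison of A4.1 with IgM asked what the neutralizing antibody changed in cells given rThbs1. Of 32 interferon response genes 14 fell with A4.1 (median log2 fold change -0.92), and of 24 p53 targets 5 rose (median 0.47). Rtp4, an interferon-induced chaperone, fell from 50.6 ± 1.89 to 5.33 ± 1.51 FPKM (SD, n = 3 and 3; log2 fold change -3.05, SE 0.17, adjusted p = 1.29e-07; ENSMUSG00000033355, GRCm38 chr16:23520291-23614222). Irf7, a master regulator of type I interferon, fell from 13.8 ± 1.41 to 1.48 ± 0.505 FPKM (log2 fold change -2.59, SE 0.22, adjusted p = 1.3e-05; ENSMUSG00000025498, chr7:141262706-141266481). Serpine2, a secreted serine protease inhibitor, rose from 3.07 ± 1.05 to 20.4 ± 1.78 FPKM (log2 fold change 2.42, SE 0.20, adjusted p = 1.3e-05; ENSMUSG00000026249, chr1:79794197-79861180). Of 10932 genes, 60 rose and 33 fell, 88 of the 93 were protein coding, and all 93 had groups that did not overlap (12.9% of all genes did so, where chance gives 10%).

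Of the interferon list 23 members fell when adjusted over the list alone (adjusted p = 0.00076 with an estimated correlation). Ifi27l2a fell from 28.2 ± 4.61 to 4.83 ± 2.53 FPKM (adjusted p = 0.000913), Oasl2 from 11.4 ± 1.24 to 2.31 ± 0.624 (adjusted p = 0.000113), and Ifit1 from 4.73 ± 2.29 to 0.35 ± 0.278 (adjusted p = 0.00274). Xaf1, an interferon-induced pro-apoptotic factor, changed by -1.48 (adjusted p = 0.000105). Cox6a2, a muscle isoform of a cytochrome c oxidase subunit, fell by a log2 fold change of 1.81 (adjusted p = 0.00253), while Cox6b2, a testis isoform of another subunit, rose by 1.45 (adjusted p = 0.000905). Of the p53 list 14 members rose when adjusted over the list alone (adjusted p = 0.0199 with an estimated correlation). Perp, a p53 target at cell junctions, rose from 69.7 ± 7.25 to 149 ± 10.7 FPKM (adjusted p = 0.000172) and Cdkn1a from 255 ± 24.9 to 467 ± 55.7 (log2 fold change 0.87, SE 0.12, adjusted p = 0.000913). Btg2 (1.05, adjusted p = 0.00481) and Phlda3 (0.82, adjusted p = 0.00866), another p53 target, also rose.

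Of 10 neutrophil and granule genes 3 rose with A4.1 and 1 fell, and 9 rose and 1 fell when adjusted over the list alone (median 0.78; adjusted p = 0.0526 with an estimated correlation). Ctsg, the serine protease cathepsin G, rose from 34.3 ± 4.63 to 63.0 ± 1.57 FPKM (adjusted p = 0.00315). Prtn3, proteinase of the same granules (0.81, adjusted p = 0.0396), and Pglyrp1, a peptidoglycan-binding granule protein (0.83, adjusted p = 0.025), rose as well. Gfi1, a transcriptional repressor of granulocyte development, fell by a log2 fold change of 0.84 (adjusted p = 0.0407). Of 14 mast cell and basophil genes 4 rose, with 4 adjusted over the list alone (median 0.53, or 0.304 without A4.1 replicate 2; adjusted p = 0.143 with an estimated correlation). Mcpt8, a basophil protease, rose from 29.8 ± 2.17 to 76.4 ± 15.2 FPKM (adjusted p = 0.00168), and Gzmb, granzyme B, by a log2 fold change of 0.89 (adjusted p = 0.00641). Ccl9, a chemokine, was at 0.84 (adjusted p = 0.0107) and Csf2rb2, a cytokine receptor chain, at 0.74 (adjusted p = 0.00866). Alox5, which makes leukotrienes, rose from 26.4 ± 4.05 to 68.7 ± 11.2 FPKM (adjusted p = 0.000172). Sulf2, an extracellular heparan sulfatase, rose from 3.95 ± 0.511 to 13.03 ± 1.79 FPKM (adjusted p = 0.00031). Mmp2, a matrix metalloprotease, rose by a log2 fold change of 1.37 (adjusted p = 0.0328), and Fbp1, a gluconeogenic enzyme, by 1.40 (adjusted p = 0.0335). Cd68 (1.08, adjusted p = 0.00051), a lysosomal protein of macrophages, and Tyrobp (1.14, adjusted p = 0.00361), a myeloid signalling adaptor, rose, while the monocyte list had 2 of 9 members higher and 1 lower and did not pass (median 0.40, mean 0.04, adjusted p = 0.261).

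Of 23 NF-kB and inflammatory genes 2 rose, Il1b (1.29, adjusted p = 0.0328) and Nfkbia (0.61, adjusted p = 0.0331), the cytokine and the pathway's inhibitor, and 6 rose and 1 fell when adjusted over the list alone (median 0.11; adjusted p = 0.211 with an estimated correlation). Of 25 cholesterol synthesis genes 2 rose, Mvd (0.61, adjusted p = 0.0396) and Pcsk9 (0.89, adjusted p = 0.0437), with 2 adjusted over the list alone (median 0.22; adjusted p = 0.216 with an estimated correlation). Of 22 red-ox genes Nqo1, an NRF2 target, rose by a log2 fold change of 0.81 (adjusted p = 0.0103), and 3 rose adjusted over the list alone (median 0.22; adjusted p = 0.143 with an estimated correlation). The G2/M list passed at a median of 0.22 with 5 of 30 members higher adjusted over the list alone and Gtse1, a mitotic p53 regulator, called (0.74, adjusted p = 0.0494; adjusted p = 0.216 for the list with an estimated correlation). The TGF-beta and SMAD list passed at 0.16 with Cdkn1a its called member (adjusted p = 0.216 with an estimated correlation). Lists that passed on the higher side with 0 called members were HSC ageing signature (median 0.33), megakaryocyte (0.20), adhesion (0.13), histone genes (0.25), immediate early genes (0.18) and ribosomal proteins (0.15). Members higher adjusted over the list alone were 4 (and 1 lower), 6, 4, 0, 1 and 0, and their adjusted p with an estimated correlation were 0.282, 0.127, 0.282, 0.282, 0.216 and 0.652, and the ribosomal median turned to -0.00333 with quantile normalization. MYC and ribosome biogenesis passed on the lower side with 0 called members (median -0.06; adjusted p = 0.346 with an estimated correlation). Its median turned to 0.00640 without A4.1 replicate 3 and was -0.151 and -0.0836 without A4.1 replicates 1 and 2. The ribosomal median was 0.0945, 0.287 and 0.0749 without A4.1 replicates 1, 2 and 3 and 0.0521 without IgM replicate 1, and the NF-kB median 0.173 without A4.1 replicate 2 and 0.181 and 0.0606 without IgM replicates 1 and 2. Without A4.1 replicate 1 the TGF-beta median was 0.104, without A4.1 replicate 2 the G2/M median was 0.136, and without IgM replicate 2 the HSC ageing median was 0.202. The megakaryocyte median was 0.130 without A4.1 replicate 3 and 0.0810 and 0.328 without IgM replicates 1 and 3, and the immediate early median 0.0973 and 0.312 without the same IgM replicates. Histone genes were at 0.128 without IgM replicate 1, and cholesterol and adhesion at 0.339 and 0.0811 without IgM replicate 3. TPM rescaling turned the NF-kB, ribosomal and adhesion medians to -0.0154, -0.0179 and -0.0237.

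In the integrated stress and unfolded protein response list Ddit4, an mTORC1 inhibitor, rose by a log2 fold change of 0.85 (adjusted p = 0.0247) and Ddit3, the stress factor CHOP, fell by 0.84 (adjusted p = 0.0487), and the list did not pass (adjusted p = 0.522). HSC identity (1 member lower), antigen presentation, S phase, mitochondrially encoded, glycolysis, lysosome, erythroid, lymphoid and heat shock lists did not pass either, at adjusted p of 0.0654 to 0.316. Oxidative phosphorylation did not pass (median 0.04, adjusted p = 0.261), and its median was -0.125 after TPM rescaling and -0.0781 with quantile normalization. Thrombospondin receptors and partners did not pass (adjusted p = 0.598), with a median and a mean of opposite sign. Hlf was at 6.07 ± 1.86 FPKM with A4.1 and 10.7 ± 1.58 with IgM (log2 fold change -0.75, adjusted p = 0.0783), Procr at -0.42 (adjusted p = 0.441), Selp at 0.34 (adjusted p = 0.583) and Cd47 at -0.03 (adjusted p = 0.976). Mki67 was at -0.66 (adjusted p = 0.766), with the 9.32 FPKM of IgM replicate 1 behind the IgM mean of 3.48. Thbs1 (0.0467 and 0.01 FPKM), Cd36 (0.09 and 0.08) and Mecom (0.667 and 0.763) lay below the filter. The count of 93 was 45 (19 higher and 26 lower) and 56 without A4.1 replicates 1 and 2, 54 and 38 (19 higher and 19 lower) without IgM replicates 1 and 2, and 15 higher and 38 lower after TPM rescaling, and 18 of the 35 called genes under the naming rule kept their call without each library. The interferon list passed with an estimated correlation in all 28 alternatives (adjusted p 0.000371 to 0.0311), and the p53 list in 24 of them (0.00606 to 0.169). The p53 list did not pass without IgM replicates 2 and 3 (0.0546 and 0.0742), after TPM rescaling (0.169, at a median of 0.267) or with only the compared groups fitted (0.109).

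**Figure D2:**
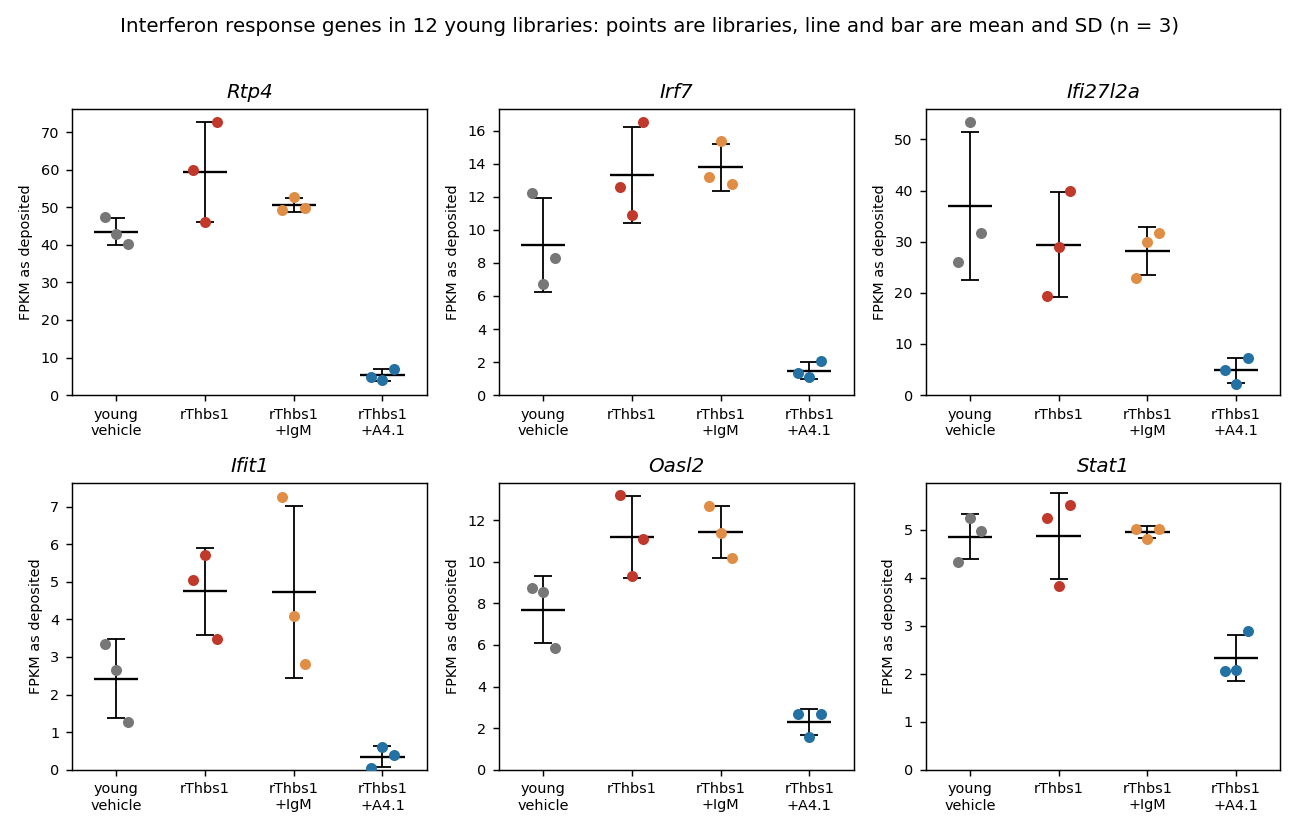
FPKM of the interferon-induced genes Rtp4, Irf7, Ifi27l2a, Ifit1, Oasl2 and Stat1 in each library of the 4 young groups, with the group mean and SD (n = 3). Rtp4 lies at a mean of 5.33 FPKM in the A4.1 group against 43.5 in young vehicle, 59.5 with rThbs1 and 50.6 in the IgM group.

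A4.1 against rThbs1 alone addressed the same antibody with no antibody in the reference group. Rtp4 fell from 59.5 ± 13.3 to 5.33 ± 1.51 FPKM (n = 3 and 3; log2 fold change -3.26, SE 0.17, adjusted p = 4.99e-08), Irf7 by a log2 fold change of 2.53 (adjusted p = 1.64e-05), and Cox6a2 changed by -2.56 (adjusted p = 5.2e-05). Serpine2 rose by 2.26 (adjusted p = 2.02e-05), Cox6b2 by 1.99 (adjusted p = 3.2e-05) and Elane, neutrophil elastase, from 0.343 ± 0.595 to 4.23 ± 2.16 FPKM (adjusted p = 0.00497). In all, 101 genes rose and 54 fell, and 145 of the 155 were protein coding. With A4.1 against IgM this comparison shared 45 higher genes, where independent lists would share 0.554, and 32 lower genes, where they would share 0.163. Simulated groups with a shared A4.1 group and no changed genes shared at most 1 gene in 20 draws. The part of the overlap due to the shared libraries was not measured.

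Of 32 interferon genes 18 fell, and 24 when adjusted over the list alone (median -0.999; adjusted p = 0.000758 with an estimated correlation), with Isg15, a ubiquitin-like modifier, at -1.65 (adjusted p = 4.77e-05). Of 10 neutrophil and granule genes 8 rose and 1 fell, and 9 rose and 1 fell when adjusted over the list alone (median 1.23; adjusted p = 0.00939 with an estimated correlation). Ctsg was at 1.44 (adjusted p = 2.02e-05), Prtn3 at 1.43 (adjusted p = 0.000216) and Gfi1 at -1.27 (adjusted p = 0.00128). Of 24 p53 genes 7 rose, and 16 when adjusted over the list alone (median 0.59; adjusted p = 0.00939 with an estimated correlation). Pmaip1, the BH3-only protein Noxa, was at 1.59 (adjusted p = 0.00497) and Plk2 at 1.28 (adjusted p = 0.00216). Of 30 G2/M genes 4 rose, and 11 when adjusted over the list alone (median 0.38; adjusted p = 0.0259 with an estimated correlation), with Ube2c, of the anaphase-promoting pathway, at 0.51 (adjusted p = 0.0153). Trib3, a stress-induced pseudokinase, changed by -1.37 (adjusted p = 0.000231), Ddit3 by -1.10 (adjusted p = 0.00504), and Ly6a, the surface antigen Sca-1, by -1.19 (adjusted p = 0.00221). Aldh1a1, a retinal dehydrogenase of the HSC ageing list, rose by 1.04 (adjusted p = 0.0468), and Hbb-bt, a beta globin, by 1.07 (adjusted p = 0.0236).

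Lists that passed only at the preset correlation in A4.1 against rThbs1 included histone genes (median 0.55, 14 of 19 higher adjusted over the list alone), megakaryocyte (0.25), red-ox (0.24) and erythroid (0.17), with adjusted p of 0.0549, 0.0933, 0.0933 and 0.114 with an estimated correlation. HSC identity (-0.05), mast cell (0.22), cholesterol (0.27), antigen presentation (-0.29) and HSC ageing signature (0.34) lost the call at 0.114, 0.114, 0.183, 0.212 and 0.231. MYC (-0.15), immediate early genes (0.21), stress response (-0.09), S phase (0.14) and mitochondrially encoded transcripts (0.42) lost it at 0.231, 0.231, 0.242, 0.339 and 0.365. The other 11 tested lists did not pass, and the ribosomal median among them was 0.08 and turned to -0.0904 without rThbs1 replicate 1. Without that replicate S phase, MYC and mast cell medians were 0.207, -0.0691 and 0.357, and without rThbs1 replicates 2 and 3 HSC ageing was at 0.170 and HSC identity at -0.0744. Without A4.1 replicate 1 HSC identity, mitochondrially encoded transcripts and stress response were at -0.00651, 0.658 and -0.142, and without A4.1 replicate 2 HSC identity, G2/M and cholesterol were at -0.147, 0.241 and 0.160. Leaving out A4.1 replicate 3 gave 0.206 for S phase, -0.0784 for MYC, 0.243 for mitochondrially encoded transcripts, -0.0200 for stress response, 0.139 for immediate early genes, 0.162 for megakaryocyte and 0.410 for mast cell. The erythroid median was 0.345 without young vehicle replicate 1, 2 or 3 or IgM replicate 3. The count of 155 was 97 and 74 without rThbs1 replicates 2 and 3, 75 (38 higher and 37 lower) and 102 without A4.1 replicates 1 and 2, and 40 higher and 61 lower after TPM rescaling. The G2/M list did not pass with an estimated correlation without rThbs1 replicates 2 and 3 (adjusted p = 0.0775 and 0.0605; 0.00912 to 0.314 over 28 alternatives), after TPM rescaling (0.314) or in a fit of the compared groups (0.133). The p53 list did not pass with it after TPM rescaling (adjusted p = 0.0831; 0.00350 to 0.111 over 28 alternatives) or in a fit of the compared groups (0.111). The granule list did not pass with it with no filter (adjusted p = 0.0528; 0.00648 to 0.133 over 28 alternatives) or in a fit of the compared groups (0.133).

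A4.1 against young vehicle asked what still differed from vehicle when rThbs1 and its antibody were both present. Rtp4 fell from 43.5 ± 3.54 to 5.33 ± 1.51 FPKM (n = 3 and 3; log2 fold change -2.84, SE 0.17, adjusted p = 3.8e-07) and Ifi27l2a by a log2 fold change of 2.74 (adjusted p = 0.000343). Ighv1-23, an immunoglobulin heavy chain segment, changed by -3.25 (adjusted p = 0.00781) and Jun by -1.87 (adjusted p = 0.00066). Sulf2 rose by 1.93 (adjusted p = 7.98e-05), Serpine2 by 1.84 (adjusted p = 0.00027) and Pmaip1 by 1.63 (adjusted p = 0.00517). In all, 81 genes rose and 52 fell. With A4.1 against IgM this comparison shared 34 higher and 24 lower genes, with the A4.1 libraries in both. Simulated groups with a shared A4.1 group and no changed genes shared 0 in 20 draws. The part of this overlap due to shared libraries was not measured.

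Of 32 interferon genes 11 fell, and 23 when adjusted over the list alone (median -0.70; adjusted p = 0.00592 with an estimated correlation), with Irf7 at 1.48 FPKM against 9.08 (adjusted p = 0.00027) and Isg15 at -1.52 (adjusted p = 0.00027). Of 22 red-ox genes 5 rose, and 9 rose and 1 fell adjusted over the list alone (median 0.19; adjusted p = 0.154 with an estimated correlation). Nqo1 was at 1.24 (adjusted p = 0.00034), Srxn1, sulfiredoxin, at 0.90 (adjusted p = 0.00123) and Cat, catalase, at 0.71 (adjusted p = 0.00421). Mpo, myeloperoxidase, rose from 118 ± 3.11 to 303 ± 95.6 FPKM (adjusted p = 0.00274), and 5 of 10 granule genes rose and 1 fell, or 8 and 1 adjusted over the list alone (median 0.92; adjusted p = 0.0515 with an estimated correlation). Of 24 p53 genes 5 rose (median 0.48), of 30 G2/M genes 2 rose (0.44), and of 16 immediate early genes 3 fell (-0.26), each list at adjusted p = 0.0507 with an estimated correlation. Adjusted over the list alone, 14 p53 genes rose and 1 fell, 14 G2/M genes rose, and 7 immediate early genes fell. Dusp1 changed by -0.93 (adjusted p = 0.00291) and Klf2, a quiescence factor, by -1.03 (adjusted p = 0.0175). Ribosomal proteins passed at -0.49 with 0 called and 41 of 47 lower adjusted over the list alone (adjusted p = 0.333 with an estimated correlation). HSC identity (-0.15), adhesion (0.18), antigen presentation (-0.30), mast cell (0.19), lysosome (0.13) and oxidative phosphorylation (-0.17) passed only at the preset correlation, with 0.154, 0.376, 0.394, 0.394, 0.518 and 0.537 as the adjusted p with an estimated correlation. The other 16 tested lists did not pass, and the erythroid list among them had a median of 0.08 and a mean of -0.07. The red-ox median was 0.294 and 0.293 without young vehicle replicates 2 and 3 and 0.352 without A4.1 replicate 2, and that of HSC identity -0.0290 without A4.1 replicate 1. Oxidative phosphorylation was at -0.110 without young vehicle replicate 2 and -0.0949 without A4.1 replicate 2. Adhesion was at 0.113 without A4.1 replicate 2, mast cell at 0.121 without young vehicle replicate 2 and lysosome at 0.196 without young vehicle replicate 1. The count of 133 was 57 and 73 without young vehicle replicates 2 and 3, and 65 (29 higher and 36 lower) and 59 without A4.1 replicates 1 and 2. The interferon list did not pass with an estimated correlation after TPM rescaling (adjusted p = 0.127; 0.00266 to 0.127 over 28 alternatives), in a fit of the compared groups (0.111) or without the 3 most AT-rich libraries (0.0598).

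IgM against young vehicle gave another estimate of the rThbs1 effect, with the IgM antibody present. Jun fell from 21.5 ± 6.77 to 2.89 ± 0.492 FPKM (n = 3 and 3; log2 fold change -2.50, SE 0.24, adjusted p = 0.000259), and S100a4 from 28.9 ± 1.37 to 9.89 ± 3.59 (adjusted p = 0.0119). Fos changed by -1.49 (adjusted p = 0.0192), mt-Rnr1 by -1.60 (adjusted p = 0.027), Dusp1 by -0.95 (adjusted p = 0.0161), Nkg7 by -0.80 (adjusted p = 0.024) and H1f2 by -0.85 (adjusted p = 0.0472). Snord69, a small nucleolar RNA, rose by 2.96 (adjusted p = 0.027), in all 1 gene higher and 22 lower (4 and 19 with quantile normalization, 5 and 19 with a correction for GC content and gene length). Of the 22 lower genes 16 also fell in rThbs1 against young vehicle, where independent lists would share 0.0604. Simulated groups with shared vehicle libraries and no changed genes shared 0 in 20 draws. How many called genes the shared libraries give in common was not measured. Of 16 immediate early genes 3 fell, and 9 when adjusted over the list alone (median -0.38; adjusted p = 0.0298 with an estimated correlation). Ribosomal proteins (-0.64, 45 of 47 lower adjusted over the list alone), cholesterol (-0.31), lymphoid (-0.33), histone (-0.25) and G2/M (0.31) lists passed at the preset correlation, each with adjusted p = 0.389 with an estimated correlation. So did interferon (0.21), MYC (0.17) and oxidative phosphorylation (-0.22), with adjusted p of 0.412, 0.552 and 0.552 with an estimated correlation, while the other 20 tested lists did not pass. The interferon and oxidative phosphorylation medians were 0.131 and -0.127 without IgM replicate 1, and the histone median -0.390 without young vehicle replicate 1. TPM rescaling turned the oxidative phosphorylation and histone medians to 0.0834 and 0.0561 and moved the immediate early median to -0.10001. Among the lists that did not pass, the p53, mitochondrially encoded and glycolysis lists differed in sign between median, mean and test. The count of 23 was 45, 9 and 1 without young vehicle replicates 1, 2 and 3, 88, 37 and 14 without rThbs1 replicates 1, 2 and 3, 15 without A4.1 replicate 3, and 3, 1 and 14 without IgM replicates 1, 2 and 3. The immediate early list did not pass with an estimated correlation in 13 of 28 alternatives (0.00968 to 0.484). It was at 0.0881 and 0.0584 without young vehicle replicates 1 and 3, 0.0773, 0.0829 and 0.0606 without the rThbs1 replicates, 0.0543 and 0.0513 without A4.1 replicates 1 and 2, and 0.0856 without IgM replicate 2.

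IgM against rThbs1 asked what the IgM antibody changed in cells given rThbs1. No gene passed in limma, with 353 at an unadjusted p under 0.05. The genes of smallest p were Gm23421, a small nuclear RNA model, at 1.56 (adjusted p = 0.176), and Ctsg (0.58), H2-M3 (-0.49), Lacc1 (0.93) and Emc2 (0.58), each at an adjusted p of 1. Mitochondrially encoded transcripts (0.70), granule genes (0.46), G2/M (0.16), histone genes (0.30), stress response (-0.11), antigen presentation (-0.15) and ribosomal proteins (-0.08) passed at the preset correlation. With an estimated correlation their adjusted p were 0.392, 0.22, 0.22, 0.316, 0.392, 0.679 and 0.887, and the ribosomal median turned to 0.0589 without rThbs1 replicate 2 and 0.0218 without IgM replicate 1. It was -0.232 without rThbs1 replicate 1 and -0.153 without IgM replicate 3. The mitochondrially encoded median was 0.224 without IgM replicate 1 and 1.07 without IgM replicate 3, and the histone median 0.194 without rThbs1 replicate 1 and 0.172 without IgM replicate 3. Stress response was at -0.0566 without rThbs1 replicate 2 and -0.0557 without IgM replicate 1, and antigen presentation at -0.0891 without IgM replicate 1. The other 22 tested lists did not pass, and the interferon, megakaryocyte, monocyte and mast cell lists among them had a median and a mean of opposite sign. The count was 1 without IgM replicate 1.

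Unblocked rThbs1 against the rest set the 6 libraries given rThbs1 without its neutralizing antibody (rThbs1 and IgM) against the other 6 young libraries (young vehicle and A4.1). Oasl2, an oligoadenylate synthetase-like protein, rose from 5.01 ± 3.15 to 11.3 ± 1.47 FPKM (SD, n = 6 and 6; log2 fold change 1.21, SE 0.14, adjusted p = 0.000385). S100a4 fell from 25.98 ± 4.31 to 9.81 ± 2.66 FPKM (log2 fold change -1.34, SE 0.15, adjusted p = 0.000323), and Nkg7 from 416 ± 80.7 to 209 ± 14.5 (log2 fold change -0.97, SE 0.09, adjusted p = 0.000101). Cdkn1a fell from 403 ± 78.6 to 260 ± 18.5 FPKM (log2 fold change -0.61, SE 0.08, adjusted p = 0.00106). Its mean was higher with A4.1 than in vehicle, and it did not pass in rThbs1 against young vehicle. In all, 42 genes rose and 107 fell (68 and 93 with a correction for GC content and gene length), 122 of the 149 were protein coding, and 41 had sides that did not overlap (0.832% of all genes did so, where chance gives 0.216%).

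Of 32 interferon genes 14 rose, and 25 when adjusted over the list alone (median 0.66; adjusted p = 0.00545 with an estimated correlation). Rtp4 rose from 24.4 ± 21.1 to 55.1 ± 9.77 FPKM (adjusted p = 3.03e-06), with sides that overlapped, at a mean of 43.5 in vehicle and 5.33 in A4.1. Irf7 (1.56, adjusted p = 0.000101), Xaf1 (0.90, adjusted p = 0.000391) and Oas1a (0.77, adjusted p = 0.000529) rose too. Apol9b (1.20, adjusted p = 0.000689), Slfn8, a Schlafen family member (1.13, adjusted p = 0.026), Tdrd7, a tudor domain protein (0.79, adjusted p = 0.0142), and Jak2, the kinase of the TPO receptor (0.80, adjusted p = 0.0334), rose outside the list. None of the 32 interferon genes passed in rThbs1 or IgM against young vehicle over all genes. Of 16 immediate early genes 3 fell, and 10 when adjusted over the list alone (median -0.37; adjusted p = 0.0225 with an estimated correlation), among them Jun (-1.39, adjusted p = 0.000611), Fos (-1.02, adjusted p = 0.00566) and Ier3 (-0.47, adjusted p = 0.0386). Of 24 p53 genes 6 fell, and 9 when adjusted over the list alone (median -0.26; adjusted p = 0.0606 with an estimated correlation). Btg2 was at -0.95 (adjusted p = 0.000689), Perp at -0.69 (adjusted p = 0.000689) and Gdf15, a stress-induced cytokine, at -0.57 (adjusted p = 0.0111). Over left-out libraries the p53 median was 0.407 to 0.569 in A4.1 against young vehicle. It was -0.186 to -0.00668 in rThbs1 and -0.0956 to 0.0801 in IgM against young vehicle, so the fall holds a rise with A4.1. Of 10 granule genes 5 fell, and 1 rose and 7 fell when adjusted over the list alone (median -0.60; adjusted p = 0.0764 with an estimated correlation). Ctsg was at -0.71 (adjusted p = 0.000841) and Prtn3 at -0.68 (adjusted p = 0.0111). Gzmb fell by 0.71 (adjusted p = 0.00251) and Mcpt8 by 0.76 (adjusted p = 0.00997), the 2 called of 14 mast cell genes, with 4 adjusted over the list alone (median -0.31; adjusted p = 0.186 with an estimated correlation). Over left-out libraries the granule median was 0.833 to 0.966 in A4.1, -0.563 to -0.303 in rThbs1 and -0.0970 to 0.0993 in IgM against young vehicle. The mast cell median was 0.121 to 0.285, -0.286 to -0.0528 and -0.135 to -0.0308 there, so both falls hold rises with A4.1. Of 19 histone genes 4 fell, and 12 when adjusted over the list alone (median -0.44; adjusted p = 0.0758 with an estimated correlation). H1f5 was at -0.68 (adjusted p = 0.0127) and H1f2 at -0.63 (adjusted p = 0.0134). H2bc8 (-1.08, adjusted p = 0.018), H3c6 (-0.83, adjusted p = 0.0205) and Snord13, a small nucleolar RNA (-0.98, adjusted p = 0.00396), were among the lowest.

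Of 25 cholesterol synthesis genes 5 fell, and 13 when adjusted over the list alone (median -0.26; adjusted p = 0.109 with an estimated correlation). Mvd was at -0.55 (adjusted p = 0.00636), Nsdhl at -0.51 (adjusted p = 0.00636) and Pcsk9 at -0.74 (adjusted p = 0.0145). Of 20 megakaryocyte genes 3 fell, and 4 when adjusted over the list alone (median -0.13; adjusted p = 0.109 with an estimated correlation), among them the platelet chemokines Pf4 (-0.49, adjusted p = 0.026) and Ppbp (-0.50, adjusted p = 0.0332). Trib3 rose by 0.63 (adjusted p = 0.0149) and Ddit4 fell by 0.62 (adjusted p = 0.018), in a stress response list that did not pass. Ribosomal proteins passed at -0.36 with 0 called and 37 of 47 lower adjusted over the list alone (adjusted p = 0.273 with an estimated correlation). Erythroid (-0.21), MYC (0.13), lymphoid (-0.30), HSC ageing signature (-0.19), red-ox (-0.10) and oxidative phosphorylation (-0.12) lists passed only at the preset correlation, with adjusted p of 0.0954, 0.24, 0.273, 0.346, 0.387 and 0.535 with an estimated correlation. With quantile normalization the red-ox median turned to 0.0211, and oxidative phosphorylation lay at -0.0183 with a test that pointed the other way. TPM rescaling turned the oxidative phosphorylation, megakaryocyte and red-ox medians to 0.0945, 0.0698 and 0.113. Oxidative phosphorylation was at -0.08 without A4.1 replicate 1 and -0.0651 without IgM replicate 1, red-ox at -0.0619 without IgM replicate 1, erythroid at -0.320 without IgM replicate 3 and lymphoid at -0.171 without rThbs1 replicate 3. The other 14 tested lists did not pass, and the HSC identity, glycolysis, thrombospondin receptor and monocyte lists among them had a median and a mean of opposite sign. Hlf (0.39, adjusted p = 0.158), Procr (0.19, adjusted p = 0.469), Selp (-0.18, adjusted p = 0.489), Cd47 (-0.03, adjusted p = 0.893) and Mki67 (0.29, adjusted p = 0.742) did not pass. Thbs1, Cd36 and Mecom lay below the filter. The count of 149 was 99 and 59 without young vehicle replicates 2 and 3, 78 and 70 without rThbs1 replicates 1 and 3, 71 and 77 without A4.1 replicates 1 and 3, 99 and 87 without IgM replicates 1 and 2. It was 84 higher and 17 lower after TPM rescaling, and 25 of the 40 called genes under the naming rule kept their call without each library. With an estimated correlation the interferon list did not pass after TPM rescaling (adjusted p = 0.0769; 0.00304 to 0.0769 over 28 alternatives), nor did the immediate early list (0.00785 to 0.0848, at a median of -0.165), which also missed without rThbs1 replicate 2 (0.0775) and IgM replicate 2 (0.0515).

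**Figure D3:**
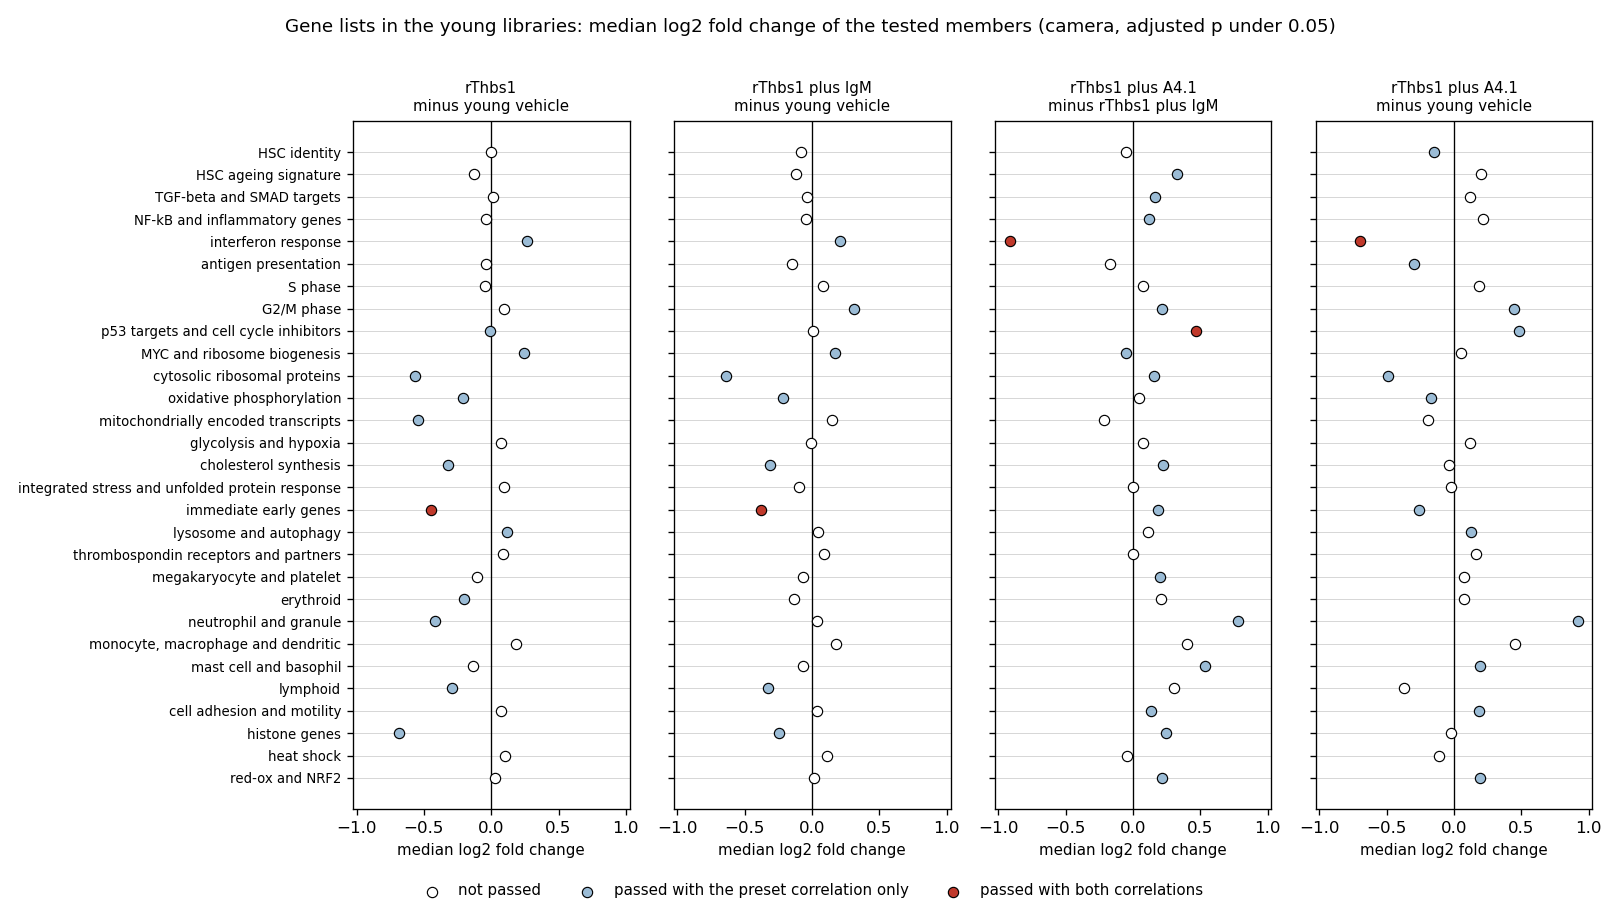
Median log2 fold change of 29 gene lists in rThbs1 against young vehicle, IgM against young vehicle, A4.1 against IgM and A4.1 against young vehicle, with the colour of each point giving the camera result (white, not passed; light blue, passed at the preset correlation only; red, passed with an estimated correlation too). The interferon list lies at -0.92 in A4.1 against IgM, and the immediate early list at -0.45 in rThbs1 against young vehicle.

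Across genes, the log2 fold changes of rThbs1 against young vehicle and of A4.1 against IgM, which share no library, had a Pearson r of -0.274 and a Spearman rho of -0.261 (jackknife SE of r 0.194). They were -0.151 and -0.108 without IgM replicate 1, -0.167 and -0.127 without A4.1 replicate 3 and -0.177 and -0.149 without rThbs1 replicate 1, and rho was -0.173 without the 3 most AT-rich libraries. Genes are not independent replicates, and 23 of 100 splits of the 12 libraries gave a correlation as far from 0. Of the 30 genes that fell with rThbs1, 3 rose in A4.1 against IgM, where independent lists would share 0.165.

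Aged against young vehicle addressed what differs between cells of 18 and 4 month old donors without added Thbs1. Stat1, which carries interferon signals, rose from 4.86 ± 0.472 to 28.3 ± 3.86 FPKM (SD, n = 3 and 3; log2 fold change 2.31, SE 0.16, adjusted p = 2.84e-09). Irf7 rose from 9.08 ± 2.84 to 33.5 ± 2.50 (log2 fold change 1.81, SE 0.20, adjusted p = 1.48e-06). Selp, P-selectin, rose from 28.3 ± 5.37 to 50.6 ± 1.73 FPKM (log2 fold change 0.83, SE 0.16, adjusted p = 0.000567). Cdkn1a fell from 339 ± 11.4 to 122 ± 3.98 FPKM (log2 fold change -1.46, SE 0.10, adjusted p = 3.23e-09) and Fos from 18.9 ± 1.40 to 1.78 ± 0.550 (log2 fold change -2.85, SE 0.24, adjusted p = 4.23e-08). Of 11224 genes 1934 were higher and 2021 lower. Of the 3955, 3238 were protein coding and 3893 had groups that did not overlap (54.6% of all genes did so, where chance gives 10%). All aged libraries belong to the set NTN and all young libraries to TSP, so age and library set cannot be told apart in any value of this comparison. After TPM rescaling 6757 genes were higher and 578 lower, and with a correction for GC content and gene length 1661 and 2837.

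Of 21 HSC ageing genes 16 rose and 2 fell, with the same counts adjusted over the list alone (median 0.91; adjusted p = 0.499 with an estimated correlation). Plscr2, a phospholipid scramblase (1.75, adjusted p = 5.03e-05), Tgm2, transglutaminase 2 (1.58, adjusted p = 3.35e-06), and Clu, the chaperone clusterin (1.57, adjusted p = 0.000195), rose, and Mt1, a metallothionein, changed by -1.83 (adjusted p = 1.37e-06). Of 32 interferon genes 21 rose and 1 fell (median 0.83; adjusted p = 0.15 with an estimated correlation), with Oasl2 at 1.49 (adjusted p = 4.15e-06). The member counted as falling, Ddx58 (6.96 ± 1.04 FPKM in young vehicle), was at 0 in all 3 aged libraries, which shows no fall. Of 24 p53 genes 11 fell (median -0.52; adjusted p = 0.341 with an estimated correlation), with Gdf15 at -1.77 (adjusted p = 9.27e-09), Btg2 at -1.54 (adjusted p = 9.85e-07) and Perp at -0.94 (adjusted p = 1.72e-05). Of 15 immediate early genes 10 fell and 1, Jund (1.49, adjusted p = 1.6e-06), rose (median -0.61; adjusted p = 0.266 with an estimated correlation), with Egr1 at -1.91 (adjusted p = 3.35e-07). Of 47 ribosomal proteins 43 fell and 1 rose (median -0.92; adjusted p = 0.683 with an estimated correlation), with Rpl23 at -1.22 (adjusted p = 2.38e-05). The member that rose, Rpl24, went from 1.66 ± 0.698 to 364 ± 28.9 FPKM (log2 fold change 7.13, SE 0.26, adjusted p = 7.75e-13). For this and other log2 fold changes of at least 3, a difference in counting between the library sets cannot be told apart from age. Of 41 oxidative phosphorylation genes 26 fell and 2 rose (median -0.36; adjusted p = 0.683 with an estimated correlation), with Cox7b at -0.94 (adjusted p = 1.56e-05) and Cox5a at 1.54 (adjusted p = 2.49e-08). Of 22 red-ox genes 17 fell and 1, the ferritin light chain Ftl1, rose (1.39, adjusted p = 1.84e-06; list median -0.60, adjusted p = 0.183 with an estimated correlation). Sod1, superoxide dismutase, was at -1.45 (adjusted p = 2.62e-05), Txn1 at -0.95 (adjusted p = 1.44e-05) and Gclm at -0.79 (adjusted p = 7.27e-06). Of 25 cholesterol genes 10 fell and 1, Fdps, rose (4.63, adjusted p = 2.88e-12; list median -0.29, adjusted p = 0.683 with an estimated correlation). Adjusted over the list alone, members higher and lower were 24 and 1 for interferon, 1 and 11 for p53, 1 and 10 for immediate early genes, 2 and 43 for ribosomal proteins, 2 and 30 for oxidative phosphorylation, 1 and 18 for red-ox and 1 and 10 for cholesterol. TPM rescaling turned the p53, oxidative phosphorylation, cholesterol and red-ox medians to 0.00158, 0.268, 0.329 and 0.0249.

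Tnf, an inflammatory cytokine, changed by -1.32 (adjusted p = 3.19e-06), Zfp36 by -1.35 (adjusted p = 2.83e-06), Egln3, an oxygen sensor, by -0.98 (adjusted p = 1.74e-06) and Esam, a stem cell adhesion marker, by 0.76 (adjusted p = 0.000223). Besides Rpl24, and with the same limit, the highest were Rnasek (6.30), Vps25 (6.30), Tomm6 (6.24), Nme2 (6.02) and Fam166a (5.93), at adjusted p of 2.01e-14, 4.54e-15, 2.3e-15, 4.74e-14 and 1.44e-11. The lowest were listed at 0 in all 3 aged libraries, so no fold is given for them. In young vehicle, mt-Co1 was at 1507.56, 1868.70 and 1878.64 FPKM, mt-Rnr2 at 1185.88, 2186.09 and 1595.91, mt-Rnr1 at 714.98, 1455.68 and 907.35, mt-Nd1 at 526.62, 726.91 and 648.84, mt-Cytb at 368.40, 442.30 and 413.61 and Skp1a, a ubiquitin ligase subunit, at 249.30, 265.13 and 290.33. The 9 mitochondrially encoded transcripts tested were listed at 0 in the aged libraries (list adjusted p = 0.15 with an estimated correlation). Of the 2021 genes counted as lower 167, Ero1l among them, were at 0 there, which shows no fall. Of the other genes, named after their values were seen, Ece2 (-3.14), Lrrc24 (-2.87), Fos, Taf6l (-2.55), Tonsl (-2.47) and Mcpt8 (-2.31) had the lowest log2 fold changes, at adjusted p of 7.83e-07 or less. Hlf (-0.45, adjusted p = 0.0537), Procr (-0.33, adjusted p = 0.118) and Mki67 (-0.14, adjusted p = 0.849) did not pass, and Cd47 (-0.16, adjusted p = 0.338) was at 0.47 after TPM rescaling. Thbs1, Cd36 and Mecom lay below the filter. The other 20 tested lists did not pass, and the TGF-beta, NF-kB and adhesion lists among them had a median and a mean of opposite sign.

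Genes that differed with age and with the antibody were compared. Of the 33 genes that fell in A4.1 against IgM, 25 were higher in aged vehicle, where independent lists would share 4.77, and of the 60 that rose 35 were lower in aged vehicle (11.2), with no library shared between the comparisons. Across all genes, the effects of age and of rThbs1 had a Pearson r of 0.267, a Spearman rho of 0.421 and a covariance of 0.0813 (jackknife SE of r 0.0973), beside 0.499, 0.472 and 0.0196 in 100 simulated draws of unchanged groups with shared controls. Set against IgM minus A4.1, which shares no library with the age comparison, they had a Pearson r of 0.0610, a Spearman rho of 0.0539 and a covariance of 0.0178 (jackknife SE of r 0.0624), and r and rho were 0.00524 and -0.00895 after TPM rescaling and 0.0120 and -0.0408 without A4.1 replicate 3. They were 0.113 and 0.102 after the GC and length correction, 0.102 and 0.108 without the 3 most AT-rich libraries, 0.0359 and 0.0131 with quantile normalization and 0.0370 and 0.0237 among nuclear coding genes. With array weights r was 0.0916. Rho was 0.0339 with no filter, 0.0812 at a mean of at least 5 FPKM, 0.0355 without young vehicle replicate 3 and 0.112 without A4.1 replicate 2. The covariance ran from 0.00215 after TPM rescaling to 0.0301 without the AT-rich libraries. That of age with rThbs1 was 0.128 without young vehicle replicate 1, 0.133 with a pseudocount of 0.1 and 0.0489 among nuclear coding genes.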

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

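The alternatives for AT-rich values, GC and length, Xist, nuclear coding genes and genes at 0 in the aged libraries were chosen only after seeing the data. The others, the gene lists and the naming rule were fixed before the data were examined.

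Over all alternatives, the side of the threshold held in 12389 tests of single named genes and 6457 of lists. Calls were gained in 290 and 132 and lost in 793 and 229, and the direction of a called test was reversed in 1 and 9. For lists that direction is camera's, taken against all other genes. The median of a passing list changed sign more often, in 25 tests of 19 lists and comparisons, 15 of them after TPM rescaling. The Pearson r of the 3 correlations across genes kept its sign throughout. The Spearman rho of age with IgM minus A4.1 changed sign after TPM rescaling and without A4.1 replicate 3. Of the 100 list tests that passed, 11 passed with an estimated correlation.

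In rThbs1 against young vehicle the count of 30 was 0 with no filter, 5 after TPM rescaling, 9 without the variance trend, 537 with array weights (133 higher and 404 lower), 7 with the other groups left out of the fit, 13 among nuclear coding genes and 18 without the 3 most AT-rich libraries. In A4.1 against IgM the count of 93 was 55 with no filter, 53 after TPM rescaling and 55 without the AT-rich libraries. In A4.1 against rThbs1 the count of 155 was 91 with no filter and 101 after TPM rescaling. In A4.1 against young vehicle the count of 133 was 71 with no filter, 528 with array weights (258 higher and 270 lower) and 234 with the GC and length correction. In IgM against young vehicle the count of 23 was 12 with a pseudocount of 0.1, 3 with no filter, 47 at a mean of at least 5 FPKM, 2 after TPM rescaling, 1 without the trend, 529 with array weights (148 higher and 381 lower) and 9 among coding genes. IgM against rThbs1 had 0 genes, and 1 with array weights. In unblocked rThbs1 against the rest the count of 149 was 39 with no filter, 96 without the trend, 355 with array weights and 89 without the AT-rich libraries. In aged against young vehicle the count of 3955 was 7335 after TPM rescaling. Asking also for a log2 fold change of at least 1 left 51 genes in A4.1 against IgM, 81 against rThbs1 and 61 against young vehicle, 13 in IgM against young vehicle, 25 in unblocked rThbs1 and 1266 with age, as a stricter rule must leave fewer. The no-filter tests cover more genes and the coding tests fewer. TPM rescaling let 12538 genes through the filter, 13044 with age, so the scaling and the genes tested changed together. For the other changes the cause was not tested.

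Leaving out 1 library at a time gave 1 to 82 genes for rThbs1 and 1 to 88 for IgM against young vehicle, 38 to 105 for A4.1 against IgM, 74 to 173 against rThbs1 and 57 to 148 against young vehicle, 0 to 1 for IgM against rThbs1, 59 to 200 for unblocked rThbs1 and 2934 to 4226 with age. Part of that follows from the smaller groups.

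With a replicate block the count was 50 for rThbs1 and 55 for IgM against young vehicle. The 18 same-number pairs of different groups correlated at -0.494 to 0.454 (median 0.0571, 5 above 0.1), beside a median of -0.0340 for different numbers. Of the libraries 6 correlated best with their own number. The 3 pairs of rThbs1 with IgM were at 0.454, 0.213 and 0.236, and those of A4.1 with IgM at -0.494, -0.212 and -0.0734. They did not show pairing over all groups. Sex went with the number in the young groups, so shared donors stay open. With the block the immediate early list had an adjusted p with an estimated correlation of 0.0513 in rThbs1 against young vehicle (0.00605 to 0.116 over 28 alternatives) and 0.0652 in IgM against young vehicle (0.00968 to 0.484). It ended no other call of a list with an estimated correlation.

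TPM rescaling moved the median of all genes to 0.267 for rThbs1, 0.307 for IgM and 0.151 for A4.1 against young vehicle, -0.141 for A4.1 against IgM, -0.105 against rThbs1, 0.203 for unblocked rThbs1 and 0.542 with age. It put oxidative phosphorylation at -0.125 in A4.1 against IgM (adjusted p = 0.0491), and Cd47 at 0.474 with age (adjusted p = 0.0234). Quantile normalization put that list at -0.0781 and ribosomal proteins at -0.00333 in A4.1 against IgM, and in unblocked rThbs1 the 2 lists oxidative phosphorylation and red-ox at -0.0183 and 0.0211. The ribosomal median ran from -0.0904 to 0.2004 over left-out libraries in A4.1 against rThbs1 and from -0.232 to 0.0589 in IgM against rThbs1, where oxidative phosphorylation ran from -0.0864 to 0.0737. Their cause was not tested.

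Recovery of simulated changes was not measured apart for genes of low expression.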

Other observations

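The tests of a return to the vehicle level, of RefSeq gene symbols and of loss of expression with age were chosen only after the result was seen.

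Between young vehicle and A4.1, Csf3r, the receptor for G-CSF, rose from 16.7 ± 1.24 to 46.0 ± 12.8 FPKM (n = 3 and 3; log2 fold change 1.37, limma adjusted p = 0.00268) and Ccl9 from 59.1 ± 14.3 to 126 ± 14.0 (adjusted p = 0.000941). Kif20a, a mitotic kinesin, rose by a log2 fold change of 0.93 (adjusted p = 0.0187), Gsr, glutathione reductase, by 0.74 (adjusted p = 0.0139) and the adhesion molecules Icam1 and Itgb2 by 0.79 and 0.61 (adjusted p = 0.0246 and 0.0175). H2-Q7, a class Ib MHC gene, fell from 129 ± 13.01 to 66.7 ± 10.5 FPKM (adjusted p = 0.000605) and Ly6a from 172 ± 21.5 to 75.9 ± 18.9 (adjusted p = 0.00278). Against rThbs1 alone, Rrm2, a subunit of ribonucleotide reductase, rose with A4.1 from 101 ± 15.4 to 170 ± 32.0 FPKM (adjusted p = 0.0156) and Hemgn, hemogen, from 22.1 ± 1.54 to 33.3 ± 2.53 (adjusted p = 0.0149). Nupr1, a stress-induced cofactor, fell there from 32.6 ± 13.1 to 11.7 ± 6.05 FPKM (adjusted p = 0.0265).

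In aged against young vehicle, lists that did not pass still held called genes of both directions. Of 26 HSC identity genes 11 were higher and 4 lower, of 20 megakaryocyte genes 6 and 1, of 32 S phase genes 2 and 10, of 10 granule genes 1 and 6, and of 23 NF-kB genes 8 and 6. Ier2, an immediate early gene, changed by -1.17 (adjusted p = 2.98e-06), Ndufa4 of the respiratory chain by -0.87 (adjusted p = 5.14e-05) and Stard4, a sterol carrier, by -0.71 (adjusted p = 4.95e-05). Of 261 processed pseudogenes called, 260 were lower in the aged libraries, and of 177 antisense genes called, 12 were lower, in values that do not say from which strand reads were counted.

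Interferon response genes were lower with A4.1 than with IgM, at a median log2 fold change of -0.916. A GC content and gene length bias is argued against as the whole source, since the median was -0.880 after correction for both (adjusted p = 0.00142 with an estimated correlation; 0.000371 to 0.0311 over 28 alternatives). A single library is argued against too, since the median nearest 0 was -0.779, without IgM replicate 1. A return to the vehicle level by itself is argued against by a median of -0.701 between A4.1 and young vehicle, where all 23 genes called over the list alone were lower. That list's call with an estimated correlation ended after TPM rescaling (adjusted p = 0.127; 0.00266 to 0.127 over 28 alternatives). An effect of the A4.1 antibody apart from Thbs1, and a difference between cultures, stay open and were not tested, as A4.1 without rThbs1 was not analysed here.

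Immediate early and ribosomal protein genes were lower with rThbs1 than with young vehicle, at medians of -0.45 and -0.56. A GC content and gene length bias is argued against for the immediate early genes, whose median was -0.416 after correction (adjusted p = 0.00605 with an estimated correlation; 0.00605 to 0.116 over 28 alternatives). For the ribosomal genes the median was -0.441 after it, and since their test did not pass with an estimated correlation before or after, a bias of this kind and a change in the cells cannot be told apart. A single library is argued against as the source of the immediate early median, which lay at -0.398 at its nearest to 0, without rThbs1 replicate 1, although the call with an estimated correlation ended without young vehicle replicate 1 (0.0752) and without rThbs1 replicates 1, 2 and 3 (0.0588, 0.0907 and 0.0546). The time from culture to lysis, to which immediate early genes respond, was not tested.

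Of the genes with a mean of at least 5 FPKM in the young libraries 99 were listed at 0 in all 3 aged libraries, among them Ddx39, Wars, Skp1a and Rn7sk, and 0 the reverse way. A loss of expression with age is argued against for the 19 mitochondrial genes with a young mean of at least 1 FPKM, all listed at 0, which living cells transcribe. Of the 99, 55.6% have a symbol that RefSeq does not use now, against 0.401% of the other genes, and of the 61 nuclear coding genes among them 44.3%. That test was found from these values, and a join by RefSeq gene symbol cannot be told apart from other steps in the processing of the set. Of genes higher by a log2 fold change of at least 3 in the aged libraries, 33.3% have at least 50% of their exon length inside another gene's exons, against 1.38% of other genes. Among protein-coding genes it is 46.9% against 1.21%. This could come from reads of overlapping genes counted in another way. Library set and age stay confounded, and other biological explanations were not tested.

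Other splits of the same libraries were counted for each comparison. For 3 against 3 libraries there are 10 splits, too few for a share under 0.05. The real counts there were 30 for rThbs1, 133 for A4.1 and 23 for IgM against young vehicle, 93 for A4.1 against IgM, 155 for A4.1 against rThbs1 and 3955 with age, and the highest other count was 0 in each. For IgM against rThbs1 it was 0, with 1 as the highest other. In unblocked rThbs1, 1 of 100 drawn splits, the real one, gave as many as 149 genes (highest other 15). The draws mixed all groups, so they cannot tell an rThbs1 effect from one of A4.1. The correlation of the rThbs1 and A4.1 effects was -0.274, and 23 of 100 drawn splits lay as far from 0, the highest of the others at 0.462, so chance is not excluded.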
